A study of Mus musculus with 24 samples.

How the data were processed

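The series holds 24 stranded poly(A) mRNA libraries from LLC1 mouse carcinoma cells, 3 in each of 8 groups defined by treatment and time. The deposited table gives TPM, in which each transcript is a share of all transcripts of its library, for 82934 transcripts in each library. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14 and quantified with kallisto 0.45, and the genome build was GRCm38. The version of the transcript set is not given in the sources used here. The column of each library summed to the same total, so TPM keeps no sequencing depth and the number of reads behind a value is unknown. The series' design text states that the authors tested differences with DESeq2 and took genes with a Bonferroni adjusted p under 0.10. A count model needs read counts, and the deposited values are TPM, so it was not used and limma on log2 values took its place.

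Transcript TPM were summed per gene with the GENCODE M21 annotation of GRCm38, which matched 79662 transcripts in 28328 genes. The other 3272 transcripts, 4.45% to 5.98% of the TPM of a library, were left out of gene values and tested by themselves. The values were then changed to log2(TPM + 1), and genes with at least 1 TPM in at least 3 of the 24 libraries were tested, 12581 in all. The pseudocount of 1 understates the change of genes at low levels. Coordinates are 1-based in GRCm38. Genes that share sequence with near-identical copies can have their reads divided differently among the copies, and some genes of families where this may occur are named as uncertain. Other members of gene families are given without that word, which does not mean that they are free of shared reads. Shared sequence was measured only for Rps12. For the other genes so named, histone genes among them, it was not checked.

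Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 24 libraries, so that the 8 groups shared 1 estimate of spread (16 residual degrees of freedom), and moderated variances with a trend on level. The two-sided p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. The 18 comparisons were each treatment against untreated cells at 6 h and 24 h, the treatments against each other at each time, the combination against the sum of the log2 effects of its parts at each time, each effect at 24 h minus that at 6 h, and untreated cells at 24 h against 6 h. The count under the series' Bonferroni rule stands beside each main count. The labels do not say whether the triplicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No library was left out, and no pair of libraries held identical values.

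Gene lists fixed before the data were examined covered ERK pathway output, interferon-stimulated genes, MHC class I presentation, chemokines, nucleic acid sensing, NF-kB targets, p53 targets, S phase and E2F targets, G2 and mitosis, folate and nucleotide synthesis, the ATF4 stress response, autophagy and mitophagy, lysosome, mitochondrially encoded mRNAs, crosslink and excision repair, cholesterol synthesis, glycolysis and hypoxia, ribosome biogenesis, matrix and mesenchymal genes, checkpoint and NK cell ligands, and the heat shock response. The lists held 504 tested members and shared none. Members below the filter were not tested and are left out of every list count. Among them were the interferon-stimulated genes Ifit1 and Rsad2 (means of 0.092 and 0.091 TPM) and the chemokines Cxcl9 and Cxcl11 (0.126 and 0.021 TPM). A gene low in most libraries could still pass the filter, such as Cxcl2 (mean 0.258 TPM). Each was tested against all other genes with camera of limma at a preset correlation between genes of 0.01, with the correlation estimated from the data as an alternative, and adjusted over the 21 lists. Of the 103 camera calls given in the text, 24 also held with the estimated correlation, each with its value beside it. Markers of macrophages, T or NK cells, B cells, endothelium, fibroblasts, lung epithelium and red cells were read as levels.

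Genes were named by a rule fixed in advance. It takes Cxcl10 in every comparison. It then takes the 8 largest rises and 8 largest falls of each treatment against untreated cells, and 5 of each in the other pairs and in the contrast with the sum, among called genes with at least 5 TPM in the higher group and, for pairs, no overlap between libraries. Predicted genes, clone names and pseudogenes were skipped. From each list it takes up to 4 called members with the smallest p and the first 3 members. Not every gene the rule allows is named. Results for some genes are not reported here.

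The steps were tested on simulated data for chemotherapy against untreated cells at 6 h with 12581 genes. With no gene changed limma called 0 genes. Of 50 genes changed by each fold, it called 27 in the right direction at 1.25-fold, 43 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, and it called 9 of 12353 unchanged genes. A list of 28 genes raised by 1.25-fold had a camera adjusted p of 1.62e-28. The simulated noise was independent between genes, so these numbers do not show how limma or camera behaves where genes move together.

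Alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 TPM, TPM rescaled per library by the median ratio to the geometric mean library, 1 fit per time point, a term for the replicate number, 1 prior variance for all genes, the Bonferroni rule, a log2 change of at least 1, each library left out in turn, and fry of limma for the lists. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.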

Results

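Gene expression was measured by RNA sequencing in LLC1, a cell line derived from the mouse Lewis lung carcinoma, after 6 h and 24 h of drug exposure. Cells received 0.1% DMSO alone (untreated), cisplatin at 2.5 µM with pemetrexed at 2.5 µM (chemotherapy), trametinib at 10 nM, or all 3 drugs (combination). Cisplatin crosslinks DNA, pemetrexed blocks folate-dependent enzymes of nucleotide synthesis, and trametinib inhibits the kinase MEK, which activates ERK. Each of the 8 groups held 3 libraries, 24 in all, and deposited values were in TPM, a share of all transcripts, so the sequencing depth behind each value is unknown. Between 11242 and 11851 genes reached 1 TPM in a library. Libraries of 1 group correlated at 0.982 to 0.994 on the log2 scale, and 12581 of 28328 genes were tested. In what follows, a change is a log2 difference in TPM + 1 with its standard error (n = 3 libraries per group), and rose, fell, higher and lower are used of genes that passed limma's moderated test at the adjusted threshold. For a gene list, the bracket gives how many members passed when adjusted over the list alone and the result of limma's camera test against all other genes.

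The series title names induction of CXCL10, a chemokine that draws activated T cells through the receptor CXCR3. Its gene, Cxcl10 (ENSMUSG00000034855.13), lies on chromosome 5 at 92346638 to 92348889 in GRCm38. In untreated cells Cxcl10 stood at 0.168 ± 0.057 TPM at 6 h and 0.414 ± 0.037 TPM at 24 h (mean ± SD, n = 3). At 6 h the level was 0.383 ± 0.202 TPM with chemotherapy, 0.212 ± 0.102 TPM with trametinib and 0.473 ± 0.147 TPM with the combination. At 24 h it was 2.85 ± 0.367 TPM with chemotherapy, 0.612 ± 0.123 TPM with trametinib and 11.2 ± 1.65 TPM with the combination. The 3 combination libraries at 24 h lay between 9.82 and 13.0 TPM, above all 9 other libraries of that time. Chemotherapy raised Cxcl10 at 24 h by 1.44 ± 0.12 (adjusted p = 3.1e-09), and the combination raised it by 3.10 ± 0.12 (adjusted p = 3.2e-14). With trametinib alone the difference was 0.19 ± 0.12 (adjusted p = 0.177).
The combination exceeded chemotherapy at 24 h by 1.66 ± 0.12 (adjusted p = 6.17e-10) and trametinib by 2.91 ± 0.12 (adjusted p = 3.93e-13). It exceeded the sum of the separate effects of its parts by 1.47 ± 0.16 (adjusted p = 1.76e-06), while trametinib against chemotherapy gave -1.25 ± 0.12 (adjusted p = 1.17e-08). At 6 h only the combination against untreated cells passed the test (0.33 ± 0.12, adjusted p = 0.0190), and with the Bonferroni rule it did not. That call ended without untreated replicate 1 (0.32), untreated replicate 2 (0.31) or combination replicate 3 (0.27). The other 6 h values were 0.23 ± 0.12 for chemotherapy (adjusted p = 0.151), 0.051 ± 0.12 for trametinib (adjusted p = 0.740), 0.097 ± 0.12 for the combination against chemotherapy (adjusted p = 0.502) and 0.28 ± 0.12 against trametinib (adjusted p = 0.103). Trametinib against chemotherapy gave -0.18 ± 0.12 (adjusted p = 0.190) and the excess over the sum was 0.045 ± 0.16 (adjusted p = 0.915). These 6 values moved with single libraries but did not pass with any 1 left out, with chemotherapy at 0.12 without its replicate 2 and trametinib between -0.007 and 0.12. These levels below 1 TPM sit near the pseudocount, and with a pseudocount of 0.1 chemotherapy (0.79, adjusted p = 0.048) and the combination against trametinib (0.90, adjusted p = 0.0338) also passed at 6 h.

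**Figure D1:**
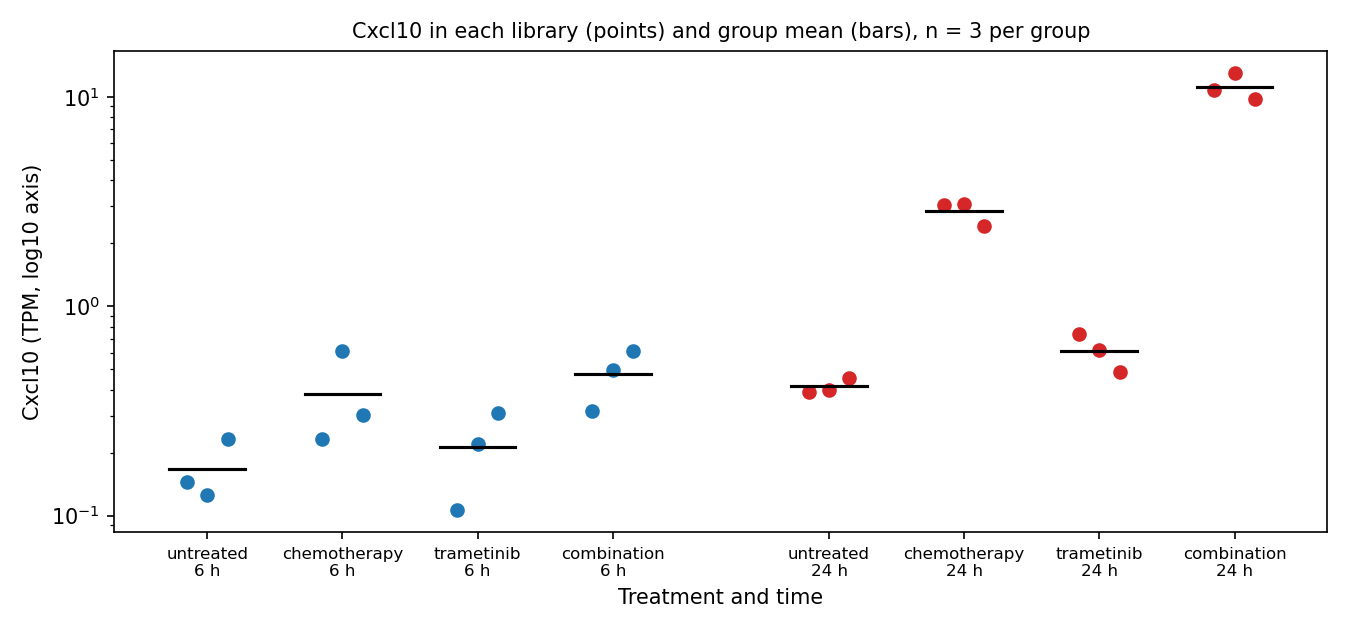
Cxcl10 in each of the 24 libraries in TPM on a log10 axis, by treatment and time. Each point is 1 library and each bar is the mean of 3. The combination libraries at 24 h lie between 9.82 and 13.0 TPM.

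After 6 h of chemotherapy, genes that p53 activates rose together. Pmaip1, which encodes the death-promoting protein Noxa, went from 2.70 ± 0.271 to 8.99 ± 0.821 TPM (1.43 ± 0.095), and Cdkn1a, which encodes the cell cycle inhibitor p21, from 114 ± 7.90 to 269 ± 56.5 TPM (1.22 ± 0.12). Trp53inp1 (1.40 ± 0.11), Pidd1 (1.07 ± 0.09), Btg2 (1.07 ± 0.076) and Mdm2, the ubiquitin ligase that degrades p53 (0.76 ± 0.088), rose as well. Of the 28 p53 targets measured, 19 rose (21 adjusted over the list alone, camera adjusted p = 5.22e-15, adjusted p = 0.0217 with an estimated correlation). Inka2, an inhibitor of the kinase PAK4, showed the highest rise (1.48 ± 0.072), and Evi2a (1.00 ± 0.097) and Necab3 (0.98 ± 0.14) were among the 8 highest.
Genes used in mitosis fell, 30 of 34 (1 up and 30 down adjusted over the list alone, camera adjusted p = 4.16e-28, adjusted p = 0.0217 with an estimated correlation). Among them were the mitotic kinase gene Plk1 (-1.03 ± 0.11), Cdc20 (-1.07 ± 0.087), Ccnb1 (-0.89 ± 0.06) and the kinetochore motor gene Cenpe (-1.23 ± 0.082). Outside the list, the spindle gene Aspm (-1.37 ± 0.099), Prr11 (-1.25 ± 0.074), Arhgap19 (-1.46 ± 0.07) and the helicase gene Pif1 (-1.59 ± 0.14) fell. In contrast, 27 of 32 genes of S phase and E2F targets rose (28 adjusted over the list alone, camera adjusted p = 1.3e-17, adjusted p = 0.0217 with an estimated correlation). Ccne1 changed by 0.79 ± 0.079, the replication licensing gene Cdc6 by 0.68 ± 0.078 and Pcna by 0.53 ± 0.054. The linker histone genes Hist1h1c (-1.70 ± 0.13) and H1f0 (-1.47 ± 0.059) also gave lower values. They are named as uncertain because some histone genes share sequence, which was not checked for these. Pard3 (-1.25 ± 0.13) and Atg7 (-0.84 ± 0.10), which fell, span 548394 and 217518 bases of genome.
Tyms, the gene of the thymidylate synthase that pemetrexed inhibits, rose by 0.44 ± 0.072. Folate and nucleotide synthesis genes as a list went both ways, 7 up and 3 down of 32 (7 up and 3 down adjusted over the list alone, camera adjusted p = 0.165). So did genes of crosslink and excision repair, 7 up and 2 down of 28 (7 up and 3 down adjusted over the list alone, camera adjusted p = 0.126), a list that passed with genes limited to a mean of 5 TPM (adjusted p = 0.0426) and with fry (adjusted p = 0.0329). Ercc5 changed by 0.68 ± 0.062. Targets of the stress-induced transcription factor ATF4 fell, 24 of 33 (26 adjusted over the list alone, camera adjusted p = 4.1e-10, adjusted p = 0.0674 with an estimated correlation). Trib3 (-0.59 ± 0.12) and the amino acid transporter gene Slc7a5 (-0.63 ± 0.071) were among them. Cholesterol synthesis genes rose in 13 of 23 cases (17 adjusted over the list alone, camera adjusted p = 7.3e-08, adjusted p = 0.0930 with an estimated correlation). Idi1 changed by 0.82 ± 0.088.
Ccl2, which encodes a monocyte-attracting chemokine, went from 45.4 ± 1.77 to 81.5 ± 15.8 TPM (0.81 ± 0.12), and 5 of 12 chemokines rose (6 adjusted over the list alone, camera adjusted p = 0.0103, adjusted p = 0.171 with an estimated correlation). Of 30 interferon-stimulated genes, 8 rose (10 adjusted over the list alone, camera adjusted p = 3.55e-04, adjusted p = 0.0966 with an estimated correlation). Irf1, a transcription factor of the interferon response, rose by 0.70 ± 0.062. Checkpoint and NK cell ligands rose in 5 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.00345, adjusted p = 0.0930 with an estimated correlation), with Cd274, which encodes PD-L1, at 0.34 ± 0.087. Heat shock genes rose in 5 of 13 cases (6 adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.215 with an estimated correlation), a list call that ended without untreated replicate 1 (adjusted p = 0.0523). Among ERK-dependent genes 3 rose and 3 fell of 27 (3 up and 3 down adjusted over the list alone, camera adjusted p = 0.903), with a median of -0.018 and a mean of 0.049. In all, 3116 genes passed the test, 1423 higher (45.7%, or 50.6% after rescaling TPM per library by a median ratio) and 1693 lower. The Bonferroni rule of the series' design text gave 566. Without chemotherapy replicate 2 the lower genes numbered 1106.

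Trametinib at 6 h lowered the genes whose transcription follows ERK activity. The feedback inhibitor genes Spry4 (-2.12 ± 0.17) and Dusp6 (-1.57 ± 0.14) and the ETS factor gene Etv4 (-2.30 ± 0.19) fell, and 21 of 27 genes of ERK output were lower against 1 higher (1 up and 21 down adjusted over the list alone, camera adjusted p = 9.29e-13, adjusted p = 0.149 with an estimated correlation). Wnt7b, a secreted signalling protein gene, fell from 21.3 ± 0.958 to 1.10 ± 0.414 TPM (-3.43 ± 0.14) and Hmga2, a chromatin architecture gene, from 323 ± 7.95 to 55.9 ± 11.5 TPM (-2.53 ± 0.10). The genes of the EGF receptor ligands amphiregulin (Areg, -2.51 ± 0.10) and HB-EGF (Hbegf, -2.31 ± 0.082) fell too, as did Sh2d5 (-2.66 ± 0.078).
ATF4 targets were lower in 31 of 33 cases (31 adjusted over the list alone, camera adjusted p = 4.59e-24, adjusted p = 0.00782 with an estimated correlation), including Trib3 (-2.77 ± 0.12), Chac1 (-3.03 ± 0.14), Cth (-2.58 ± 0.10) and the asparagine synthetase gene Asns (-1.45 ± 0.053), and Atf4 itself changed by -1.35 ± 0.055. All 27 ribosome biogenesis genes measured fell (27 adjusted over the list alone, camera adjusted p = 5.08e-20, adjusted p = 0.0820 with an estimated correlation). Nop16 (-1.18 ± 0.061) and Nolc1 (-1.20 ± 0.068) were among them. Folate and nucleotide synthesis genes fell in 24 of 32 cases and rose in 2 (2 up and 24 down adjusted over the list alone, camera adjusted p = 4.73e-10, adjusted p = 0.139 with an estimated correlation). The mitochondrial folate enzyme gene Mthfd2 changed by -1.61 ± 0.063 and Aldh1l2 by -1.77 ± 0.15.
Tgfbi, a gene for a secreted matrix protein, rose from 4.83 ± 0.140 to 43.0 ± 8.76 TPM (2.90 ± 0.12). Selenbp1 (2.88 ± 0.15), the carbonyl reductase gene Cbr2 (2.77 ± 0.20), the MYC antagonist gene Mxd4 (2.56 ± 0.10), Lrrc15 (2.43 ± 0.16), Tppp3 (2.34 ± 0.18), Cdc42ep2 (2.33 ± 0.084) and the small heat shock protein gene Cryab (2.31 ± 0.13) were also among the 8 highest rises. Acta2, which encodes smooth muscle actin, rose by 1.83 ± 0.098, Col3a1 by 1.20 ± 0.088, and the matrix protease gene Mmp3 fell (-1.71 ± 0.086). Cholesterol synthesis genes rose in 21 of 23 cases (21 adjusted over the list alone, camera adjusted p = 4.68e-06, adjusted p = 0.174 with an estimated correlation). Autophagy and mitophagy genes rose in 16 and fell in 4 of 26 cases (16 up and 4 down adjusted over the list alone, camera adjusted p = 0.0310, adjusted p = 0.312 with an estimated correlation). Optn changed by 1.17 ± 0.11 and Bnip3 by 1.26 ± 0.12. Lysosome genes rose in 19 and fell in 2 of 29 cases (19 up and 3 down adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.312 with an estimated correlation). Grn (0.76 ± 0.06) was among those that rose.
Of 30 interferon-stimulated genes, 21 rose and 1 fell (21 up and 2 down adjusted over the list alone, camera adjusted p = 2.66e-04, adjusted p = 0.149 with an estimated correlation). Stat2 (1.30 ± 0.098), Parp9 (1.29 ± 0.09) and Irf1 (1.32 ± 0.062) were higher. Chemokines went both ways, 7 up and 3 down of 12 (7 up and 3 down adjusted over the list alone, camera adjusted p = 0.379). The neutrophil-attracting Cxcl5 changed by 2.10 ± 0.12 and Ccl7 by 1.78 ± 0.13. Genes of G2 and mitosis rose in 28 of 34 cases (30 adjusted over the list alone, camera adjusted p = 2.43e-05, adjusted p = 0.349 with an estimated correlation). Nusap1 (0.99 ± 0.079) was among them. The test called 6892 genes, 4515 higher (65.5%, or 56.3% after rescaling) and 2377 lower, with 2696 under the Bonferroni rule.

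At 6 h the combination lowered ERK-dependent genes and raised p53 targets. ERK output genes fell in 22 of 27 cases and rose in 2 (2 up and 23 down adjusted over the list alone, camera adjusted p = 8.4e-12, adjusted p = 0.153 with an estimated correlation). Etv4 changed by -2.46 ± 0.19. Of 28 p53 targets, 20 rose and 4 fell (20 up and 4 down adjusted over the list alone, camera adjusted p = 8.3e-05, adjusted p = 0.157 with an estimated correlation). Cdkn1a changed by 1.12 ± 0.12, Btg2 by 1.95 ± 0.076 and Trp53inp1 by 2.89 ± 0.11. Cryab showed the highest rise, from 0.695 ± 0.0902 to 21.2 ± 1.04 TPM (3.71 ± 0.13), and Tgfbi (3.09 ± 0.12), Cbr2 (3.30 ± 0.20), Selenbp1 (2.98 ± 0.15), the annexin gene Anxa8 (2.90 ± 0.11) and Tppp3 (2.85 ± 0.18) followed. Wnt7b (-3.68 ± 0.14), Hmga2 (-2.74 ± 0.10), Chac1 (-3.06 ± 0.14), Sh2d5 (-2.69 ± 0.078), Etv5 (-2.47 ± 0.20) and Ccbe1 (-2.28 ± 0.098) fell.
Interferon-stimulated genes rose in 24 of 30 cases (24 adjusted over the list alone, camera adjusted p = 2.44e-06, adjusted p = 0.0688 with an estimated correlation). Isg15 changed by 1.69 ± 0.18 and Herc6 by 1.46 ± 0.086. Genes for presentation on MHC class I rose in 15 and fell in 2 of 22 cases (15 up and 2 down adjusted over the list alone, camera adjusted p = 0.0379, adjusted p = 0.153 with an estimated correlation). The peptide transporter gene Tap1 (1.75 ± 0.17) and B2m, the light chain gene (0.25 ± 0.039), rose. Nucleic acid sensing genes rose in 14 and fell in 1 of 18 cases (14 up and 1 down adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.160 with an estimated correlation). The double-stranded RNA receptor gene Tlr3 (1.00 ± 0.093) was among those that rose. Chemokines rose in 8 and fell in 1 of 12 cases (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.0810), a list that passed after rescaling (adjusted p = 0.044). Ccl7 changed by 2.70 ± 0.13 and Cxcl5 by 2.77 ± 0.12. The galectin gene Lgals9 rose by 1.24 ± 0.053.
S phase genes rose in 29 of 32 cases (29 up and 1 down adjusted over the list alone, camera adjusted p = 3.59e-08, adjusted p = 0.153 with an estimated correlation). Genes of G2 and mitosis went both ways, 11 up and 14 down of 34 (11 up and 15 down adjusted over the list alone, camera adjusted p = 0.0162, adjusted p = 0.569 with an estimated correlation). Plk1 changed by -0.90 ± 0.11 and Ccnb1 by -0.54 ± 0.06. ATF4 targets fell in 30 of 33 cases (30 adjusted over the list alone, camera adjusted p = 7.1e-20, adjusted p = 0.0189 with an estimated correlation), including Slc7a5 (-1.95 ± 0.071) and Trib3 (-2.56 ± 0.12). All 27 ribosome biogenesis genes measured also fell (27 adjusted over the list alone, camera adjusted p = 7.1e-20, adjusted p = 0.0688 with an estimated correlation). The test called 7347 genes, 4855 higher (66.1%) and 2492 lower, and 3297 passed the Bonferroni rule. After rescaling the higher share was 55.2%.

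Added to chemotherapy for 6 h, trametinib raised Cryab (3.56 ± 0.13), Tgfbi (3.08 ± 0.12), Cbr2 (2.93 ± 0.20), Anxa8 (2.76 ± 0.11) and Lrrc15 (2.61 ± 0.16). It lowered Wnt7b (-3.41 ± 0.14), Sh2d5 (-2.92 ± 0.078), the cytokine gene Il11 (-2.74 ± 0.21), the E-selectin gene Sele (-2.48 ± 0.077) and Etv4 (-2.48 ± 0.19). ERK output genes fell in 23 of 27 cases and rose in 1 (1 up and 23 down adjusted over the list alone, camera adjusted p = 8.09e-16, adjusted p = 0.108 with an estimated correlation). ATF4 targets fell in 28 of 33 cases (28 adjusted over the list alone, camera adjusted p = 4.77e-18, adjusted p = 0.0301 with an estimated correlation). Of 27 ribosome biogenesis genes, 27 fell (27 adjusted over the list alone, camera adjusted p = 3.52e-21, adjusted p = 0.0648 with an estimated correlation). Interferon-stimulated genes rose in 22 and fell in 2 of 30 cases (23 up and 2 down adjusted over the list alone, camera adjusted p = 9.55e-05, adjusted p = 0.108 with an estimated correlation). Genes of G2 and mitosis rose in 30 of 34 cases (31 adjusted over the list alone, camera adjusted p = 2.83e-07, adjusted p = 0.321 with an estimated correlation). Between these groups 7046 genes differed, 4989 higher in the combination (70.8%) and 2057 lower, with 2711 under the Bonferroni rule. Rescaling moved the higher share to 55.1% and the median change over all genes tested from 0.13 to 0.025.

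Chemotherapy added to trametinib for 6 h raised p53 targets. Pmaip1 rose by 1.67 ± 0.095, Trp53inp1 by 1.46 ± 0.11, Inka2 by 1.40 ± 0.072, Cryab by 1.40 ± 0.13, Cdkn1a by 0.91 ± 0.12 and Mdm2 by 0.83 ± 0.088, and 23 of 28 p53 targets were higher (24 adjusted over the list alone, camera adjusted p = 6.82e-21, adjusted p = 0.00718 with an estimated correlation). S phase genes rose in 28 of 32 cases (29 adjusted over the list alone, camera adjusted p = 2.29e-22, adjusted p = 0.0124 with an estimated correlation). Cdc6 changed by 0.93 ± 0.078 and Ccne1 by 0.91 ± 0.079. Genes of G2 and mitosis fell in 24 and rose in 1 of 34 cases (1 up and 26 down adjusted over the list alone, camera adjusted p = 6.87e-28, adjusted p = 0.0158 with an estimated correlation). Plk1 changed by -1.23 ± 0.11 and Cdc20 by -1.09 ± 0.087. Pif1 (-1.44 ± 0.14) and Sapcd2 (-1.36 ± 0.18) were also lower, beside uncertain falls of the histone genes Hist1h1c (-1.68 ± 0.13), H1f0 (-1.52 ± 0.059) and H2afx (-1.43 ± 0.13). Interferon-stimulated genes rose in 16 of 30 cases (17 adjusted over the list alone, camera adjusted p = 7.11e-07, adjusted p = 0.0369 with an estimated correlation). Isg15 (0.78 ± 0.18) and Dtx3l (0.51 ± 0.069) were among them. The comparison held 2373 called genes, 1552 higher (65.4%, or 54% after rescaling) and 821 lower, or 539 lower without combination replicate 2, and 435 passed the Bonferroni rule.

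Set directly against chemotherapy at 6 h, trametinib gave higher Tgfbi (2.89 ± 0.12), Lrrc15 (2.51 ± 0.16), Cbr2 (2.39 ± 0.20) and Atoh8 (2.41 ± 0.075) and lower Areg (-3.17 ± 0.10), Wnt7b (-3.15 ± 0.14), Il11 (-2.79 ± 0.21) and Sele (-2.52 ± 0.077). Mitotic genes were higher in 32 of 34 cases (32 adjusted over the list alone, camera adjusted p = 1.55e-15, adjusted p = 0.0911 with an estimated correlation), with Nusap1 at 1.94 ± 0.079 and Plk1 at 1.37 ± 0.11. Pmaip1 (-1.62 ± 0.095) and Cdkn1a (-1.01 ± 0.12) were lower. ATF4 targets were lower in 28 of 33 cases (29 adjusted over the list alone, camera adjusted p = 4.41e-17, adjusted p = 0.0352 with an estimated correlation). Trib3 (-2.18 ± 0.12) and Cth (-2.11 ± 0.10) were among them. The test called 7114 genes, 4641 higher with trametinib (65.2%, or 53.6% after rescaling) and 2473 lower, and 2868 with the Bonferroni rule.

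Few genes at 6 h departed from the sum of the separate log2 effects, 12 in all. Cryab showed the highest excess (1.24 ± 0.19), and the lipoprotein receptor gene Vldlr (0.87 ± 0.12) and the stress-induced factor gene Ddit3 (0.77 ± 0.096) were among the 5 highest. ATF4 targets lay above the sum in 4 of 33 cases, a number that rose to 28 when adjusted over the list alone (camera adjusted p = 6.6e-20, adjusted p = 0.0185 with an estimated correlation). The count of 12 (11 above and 1 below, 4 with the Bonferroni rule) moved with single libraries, from 3 without untreated replicate 1 to 41 without trametinib replicate 2, and was 0 with 1 limma fit per time point, where 1183 genes had an unadjusted p under 0.05. Cryab also lost its call with a pseudocount of 0.1, where its excess was 1.19 (adjusted p = 0.0701).

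After 24 h of chemotherapy p53 targets were higher. Mdm2 went from 117 ± 6.25 to 499 ± 25.1 TPM (2.08 ± 0.088), Pmaip1 from 6.09 ± 0.544 to 79.2 ± 4.80 TPM (3.50 ± 0.095) and Btg2 rose by 2.37 ± 0.076, and 19 of 28 p53 targets rose against 3 that fell (19 up and 3 down adjusted over the list alone, camera adjusted p = 1.14e-05, adjusted p = 0.198 with an estimated correlation). Txnip, which encodes the thioredoxin-interacting protein, had the highest rise, from 24.7 ± 1.15 to 621 ± 33.0 TPM (4.60 ± 0.13). Anxa8 (3.76 ± 0.11), the calcium-binding protein gene Calb1 (3.63 ± 0.69), Atg9b (3.43 ± 0.081) and Crip2 (3.43 ± 0.15) rose as well. So did Bglap2 (3.52 ± 0.24) and Ces2g (3.44 ± 0.081), named as uncertain because neighbouring genes may share their reads, which was not checked.
All 32 S phase genes measured rose (32 adjusted over the list alone, camera adjusted p = 2.74e-17, adjusted p = 0.0656 with an estimated correlation). Ccne2 changed by 3.21 ± 0.12, Cdc6 by 2.53 ± 0.078 and Slbp by 1.95 ± 0.084. Most S phase genes were lower in untreated cells at 24 h than at 6 h. Tyms (1.20 ± 0.072) and the ribonucleotide reductase gene Rrm2 (1.51 ± 0.077) were higher. Genes of glycolysis and the hypoxia response fell in 20 of 23 cases (20 adjusted over the list alone, camera adjusted p = 7.26e-07, adjusted p = 0.210 with an estimated correlation). Pkm (-0.63 ± 0.049) and Vegfa (-0.98 ± 0.071) were among them. ATF4 targets fell in 22 and rose in 5 of 33 cases (5 up and 22 down adjusted over the list alone, camera adjusted p = 2e-05, adjusted p = 0.224 with an estimated correlation). Mitochondrially encoded mRNAs rose in 7 of 13 cases (7 adjusted over the list alone, camera adjusted p = 0.0255, adjusted p = 0.431 with an estimated correlation), which did not pass after rescaling (adjusted p = 0.0679). Their share of all TPM was 9.70% in untreated and 11.5% in treated libraries.
Of 30 interferon-stimulated genes, 18 rose (18 adjusted over the list alone, camera adjusted p = 0.00484, adjusted p = 0.225 with an estimated correlation), with Lgals3bp at 1.48 ± 0.088. Irf1 (1.24 ± 0.062) and Tmem173, which encodes the sensor adaptor STING (0.91 ± 0.05), were higher. MHC class I genes rose in 14 and fell in 3 of 22 cases (14 up and 3 down adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.198 with an estimated correlation). Chemokines rose in 7 of 12 cases (7 adjusted over the list alone, camera adjusted p = 0.0218, adjusted p = 0.237 with an estimated correlation). Cxcl1 (1.67 ± 0.12) and Cx3cl1 (1.04 ± 0.081) were among them. Checkpoint and NK cell ligands rose in 9 of 12 cases (9 adjusted over the list alone, camera adjusted p = 0.00751, adjusted p = 0.198 with an estimated correlation). The costimulatory ligand gene Cd80 went from 0.630 ± 0.0602 to 11.2 ± 0.941 TPM (2.90 ± 0.087) and Cd274 rose by 0.60 ± 0.087. The list calls of chemokines and of these ligands ended with genes limited to a mean of 5 TPM (adjusted p = 0.129 and 0.0575). The inhibitor gene Nfkbia (1.68 ± 0.085) and Nfkb2 (1.21 ± 0.091) of the NF-kB pathway, the chaperone gene Dnajb1 (1.41 ± 0.055) and Egr1 (2.58 ± 0.099) rose. Beside these groups the endothelial marker Pecam1 was 3.06 ± 0.524 TPM in untreated and 9.64 ± 2.91 TPM in treated cells.
Of the 8 largest falls, 6 were in genes that span between 363246 and 1041189 bases of genome. These were Trappc9 (-3.20 ± 0.078), Immp2l (-3.19 ± 0.22), Cdh13 (-3.03 ± 0.11), Gtdc1 (-2.88 ± 0.12), Babam2 (-2.68 ± 0.13) and Cpq (-2.50 ± 0.078). The others were in histone genes, which are named as uncertain although shared reads were not checked for them. Of 23 cholesterol synthesis genes, 8 rose and 5 fell (8 up and 5 down adjusted over the list alone, camera adjusted p = 0.944), with a median of -0.02 and a mean of 0.054. Sqle fell (-1.03 ± 0.064). The test called 7447 genes, 4393 higher (59%, or 49.5% after rescaling) and 3054 lower, and 3057 passed the Bonferroni rule.

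After 24 h of trametinib, the largest rises included genes of the extracellular matrix and the actin gene Acta2. Ogn, which encodes osteoglycin, went from 3.11 ± 0.122 to 166 ± 12.0 TPM (5.34 ± 0.10), Acta2 from 6.35 ± 0.349 to 141 ± 19.8 TPM (4.26 ± 0.098) and Tgfbi rose by 4.50 ± 0.12. Omd (4.08 ± 0.09), the ceruloplasmin gene Cp (3.99 ± 0.12), the growth factor gene Ptn (3.89 ± 0.099), Cbr2 (5.13 ± 0.20), thrombospondin 1 (Thbs1, 3.15 ± 0.10) and fibronectin (Fn1, 1.08 ± 0.067) rose as well, while Mmp3 fell (-3.03 ± 0.086). Matrix and mesenchymal genes rose in 16 and fell in 7 of 25 cases (17 up and 7 down adjusted over the list alone, camera adjusted p = 0.00506, adjusted p = 0.302 with an estimated correlation). The fibroblast markers moved with this group: Col3a1 was 345 ± 13.6 TPM in untreated cells and 1090.1 ± 13.0 TPM here, and Pdgfra 4.17 ± 0.385 and 8.61 ± 0.535 TPM. The immunoglobulin gene Ighm was listed at 0 in untreated cells and had a mean of 19.7 TPM here, a value named as uncertain although shared reads were not checked.
All 23 cholesterol synthesis genes measured rose (23 adjusted over the list alone, camera adjusted p = 1.51e-15, adjusted p = 0.0248 with an estimated correlation), with a median change of 1.77. Hmgcs1 rose by 2.66 ± 0.076. ATF4 targets fell in 30 of 33 cases and rose in 1 (1 up and 30 down adjusted over the list alone, camera adjusted p = 1.9e-20, adjusted p = 0.0164 with an estimated correlation). Cth changed by -3.67 ± 0.10, Asns by -2.13 ± 0.053 and the cystine transporter gene Slc7a11 by -3.12 ± 0.11. ERK output fell in 20 of 27 cases and rose in 3 (3 up and 20 down adjusted over the list alone, camera adjusted p = 8.99e-07, adjusted p = 0.302 with an estimated correlation). Areg went from 96.2 ± 7.85 to 2.68 ± 0.483 TPM (-4.73 ± 0.10), with Dusp4 at -3.41 ± 0.17, Il11 at -3.62 ± 0.21 and Ptgs2, the cyclooxygenase 2 gene, at -3.21 ± 0.11. P2rx3, an ATP-gated channel gene, fell too (-3.07 ± 0.17). Ribosome biogenesis genes fell in 26 of 27 cases (26 adjusted over the list alone, camera adjusted p = 6.95e-09, adjusted p = 0.232 with an estimated correlation).
Targets of p53 fell in 20 and rose in 3 of 28 cases (3 up and 20 down adjusted over the list alone, camera adjusted p = 1.28e-05, adjusted p = 0.185 with an estimated correlation). Cdkn1a changed by -1.33 ± 0.12 and Mdm2 by -1.33 ± 0.088. Interferon-stimulated genes rose in 26 and fell in 1 of 30 cases (26 up and 1 down adjusted over the list alone, camera adjusted p = 6.5e-07, adjusted p = 0.0482 with an estimated correlation). Samd9l (2.11 ± 0.093), Parp9 (1.49 ± 0.09), Ifi27 (1.35 ± 0.083), Irf1 (1.51 ± 0.062) and the DNA sensor family gene Ifi204 (2.46 ± 0.12) rose. Cxcl5 (2.66 ± 0.12) and Cxcl12 (1.33 ± 0.082) rose while Ccl2 fell (-1.43 ± 0.12). Lgals9 rose (1.90 ± 0.053) and Pvr, a ligand of NK cell receptors, fell (-1.27 ± 0.055). The test called 7383 genes, 4074 higher (55.2%, or 51.6% after rescaling) and 3309 lower, and 3122 under the Bonferroni rule.

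With the combination for 24 h, interferon-stimulated genes and S phase genes rose. Among the chemokines Ccl9 had a change of 3.35 ± 0.22, Cxcl1 went from 5.90 ± 1.10 to 42.9 ± 5.76 TPM (2.67 ± 0.12), and Cxcl5 rose by 2.92 ± 0.12. In all 9 of 12 chemokines rose (9 up and 1 down adjusted over the list alone, camera adjusted p = 4.68e-04, adjusted p = 0.0945 with an estimated correlation). Interferon-stimulated genes rose in 26 of 30 cases (26 adjusted over the list alone, camera adjusted p = 5.82e-07, adjusted p = 0.0365 with an estimated correlation). Samd9l rose by 2.13 ± 0.093, Lgals3bp by 1.93 ± 0.088, Isg15 by 1.49 ± 0.18 and Irf1 by 2.02 ± 0.062. MHC class I genes rose in 17 and fell in 3 of 22 cases (18 up and 3 down adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.0365 with an estimated correlation). The heavy chain gene H2-K1 (0.62 ± 0.11), B2m (0.39 ± 0.039), Calr (1.18 ± 0.071) and Psme2 (1.34 ± 0.091) were among those that rose. Targets of NF-kB rose in 12 and fell in 3 of 17 cases (12 up and 3 down adjusted over the list alone, camera adjusted p = 0.0256, adjusted p = 0.362 with an estimated correlation), a list call that ended with genes limited to a mean of 5 TPM (adjusted p = 0.355). Nfkbia rose by 2.13 ± 0.085 and Tnfaip3 by 1.95 ± 0.073. The ligand genes Lgals9 (2.09 ± 0.053), Cd80 (1.41 ± 0.087) and Cd274 (0.39 ± 0.087) rose. Beside these groups the macrophage marker Lyz2 was 0.39 ± 0.056 TPM in untreated cells and 3.57 ± 0.351 TPM here.
All 32 S phase genes measured rose (32 adjusted over the list alone, camera adjusted p = 4.53e-14, adjusted p = 0.0365 with an estimated correlation), with Cdc6 at 2.50 ± 0.078. Here too most S phase genes were lower in the untreated cells than at 6 h. Of 34 genes of G2 and mitosis, 30 rose (30 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.309 with an estimated correlation). Kif20a changed by 1.35 ± 0.044. Of 28 p53 targets, 21 rose and 5 fell (21 up and 5 down adjusted over the list alone, camera adjusted p = 0.00318, adjusted p = 0.309 with an estimated correlation). Pmaip1 changed by 2.22 ± 0.095, Mdm2 by 0.77 ± 0.088 and Cdkn1a by 0.57 ± 0.12. ERK output genes fell in 17 and rose in 4 of 27 cases (4 up and 17 down adjusted over the list alone, camera adjusted p = 7.96e-05, adjusted p = 0.341 with an estimated correlation). ATF4 targets fell in 30 and rose in 2 of 33 cases (2 up and 30 down adjusted over the list alone, camera adjusted p = 8.5e-18, adjusted p = 0.0297 with an estimated correlation). Asns went from 422 ± 6.92 to 46.5 ± 3.36 TPM (-3.15 ± 0.053), and Trib3 (-3.18 ± 0.12), the proline synthesis gene Pycr1 (-3.26 ± 0.087) and Aldh1l2 (-3.37 ± 0.15) fell.
Txnip again had the highest rise, from 24.7 ± 1.15 to 884 ± 39.9 TPM (5.10 ± 0.13), followed by Anxa8 (4.99 ± 0.11), Angptl4 (4.60 ± 0.13), Tgfbi (4.55 ± 0.12), the dermatopontin gene Dpt (4.41 ± 0.12), Cryab (4.37 ± 0.13) and the complement protease gene C1s1 (3.75 ± 0.14). Lysosome genes rose in 23 and fell in 4 of 29 cases (23 up and 4 down adjusted over the list alone, camera adjusted p = 0.00111, adjusted p = 0.166 with an estimated correlation). Lamp2 (0.99 ± 0.055) was among those that rose. Matrix genes rose in 18 and fell in 4 of 25 cases (18 up and 4 down adjusted over the list alone, camera adjusted p = 5.41e-04, adjusted p = 0.166 with an estimated correlation), beside the fibroblast marker Dcn at 1.32 ± 0.153 TPM in untreated cells and 27.8 ± 1.06 TPM here. Cholesterol synthesis genes rose in 20 of 23 cases (20 adjusted over the list alone, camera adjusted p = 1.11e-05, adjusted p = 0.166 with an estimated correlation). Hmgcs1 changed by 1.72 ± 0.076. Il11 (-3.43 ± 0.21) and P2rx3 (-3.29 ± 0.17) fell, and Rps12 went from 425 ± 375 to 0.00810 ± 0.0128 TPM, an uncertain value in a gene with near-identical copies. The test called 7972 genes, 4977 higher (62.4%) and 2995 lower, and 3783 under the Bonferroni rule. Rescaling moved the higher share to 51.3% and the median change from 0.10 to 0.00.

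Against chemotherapy at 24 h, the combination had more Ogn (4.43 ± 0.10), Tgfbi (3.73 ± 0.12), Thbs1 (3.39 ± 0.10), Cp (3.33 ± 0.12) and Cbr2 (3.25 ± 0.20). Egr1, an early-response gene downstream of ERK, was lower (-3.52 ± 0.099), as were Calb1 (-3.36 ± 0.69), Sele (-3.05 ± 0.077), Atg9b (-2.68 ± 0.081) and Slc4a11 (-2.62 ± 0.10). Chemokines were higher in 8 and lower in 2 of 12 cases (8 up and 2 down adjusted over the list alone, camera adjusted p = 0.00688, adjusted p = 0.163 with an estimated correlation), with Cxcl5 at 2.91 ± 0.12 and Cxcl12 at 1.19 ± 0.082, a list call that ended with genes limited to a mean of 5 TPM (adjusted p = 0.291). Interferon-stimulated genes were higher in 24 and lower in 1 of 30 cases (25 up and 1 down adjusted over the list alone, camera adjusted p = 1.24e-05, adjusted p = 0.111 with an estimated correlation). Parp9 changed by 1.16 ± 0.09. Cholesterol synthesis genes were higher in 22 of 23 cases (23 adjusted over the list alone, camera adjusted p = 3.66e-09, adjusted p = 0.111 with an estimated correlation). ATF4 targets were lower in 29 and higher in 2 of 33 cases (3 up and 29 down adjusted over the list alone, camera adjusted p = 4.18e-16, adjusted p = 0.0445 with an estimated correlation). Targets of p53 were lower in 15 and higher in 4 of 28 cases (4 up and 16 down adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.213 with an estimated correlation). Mdm2 changed by -1.31 ± 0.088 and Pmaip1 by -1.28 ± 0.095. In total 6731 genes differed, 3810 higher (56.6%, or 51.9% after rescaling) and 2921 lower, 2526 of them under the Bonferroni rule.

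Against trametinib at 24 h, the combination had higher Pmaip1 (3.81 ± 0.095), the stress-induced factor gene Atf3 (3.29 ± 0.094) and Anxa8 (3.11 ± 0.11), and Cxcl10 was among the 5 highest rises. Bglap2 was listed at 0 with trametinib and had a mean of 6.80 TPM with the combination, an uncertain value. Acta2 (-2.45 ± 0.098), the asporin gene Aspn (-1.73 ± 0.094), Cdh13 (-2.10 ± 0.11) and Gtdc1 (-1.89 ± 0.12) were lower. Targets of p53 were higher in 25 and lower in 2 of 28 cases (25 up and 2 down adjusted over the list alone, camera adjusted p = 6.5e-14, adjusted p = 0.0221 with an estimated correlation). Mdm2 changed by 2.10 ± 0.088 and Cdkn1a by 1.90 ± 0.12. All 32 S phase genes measured were higher (32 adjusted over the list alone, camera adjusted p = 3.1e-17, adjusted p = 0.0221 with an estimated correlation). Chemokines were higher in 9 of 12 cases (9 adjusted over the list alone, camera adjusted p = 5.66e-05, adjusted p = 0.0542 with an estimated correlation), with Ccl7 at 2.45 ± 0.13, Cxcl1 at 2.00 ± 0.12 and Ccl2 at 1.46 ± 0.12. MHC class I genes were higher in 13 and lower in 2 of 22 cases (13 up and 2 down adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.0806 with an estimated correlation). B2m changed by 0.46 ± 0.039. Tnfaip3 (1.93 ± 0.073) and Ptgs2 (2.34 ± 0.11) were higher. Cholesterol synthesis genes were lower in 22 of 23 cases (22 adjusted over the list alone, camera adjusted p = 4.97e-16, adjusted p = 0.0221 with an estimated correlation). Fdps changed by -1.18 ± 0.084. The test called 6208 genes, 3948 higher (63.6%, or 50.3% after rescaling) and 2260 lower, and 2004 under the Bonferroni rule.

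The highest count among the pairs of groups compared was that of trametinib against chemotherapy at 24 h, 8382 genes (3922 higher with trametinib, 4460 lower, 4247 with the Bonferroni rule). The higher share of 46.8% became 50.9% after rescaling, so which direction held more genes depended on the scaling. Ogn (6.04 ± 0.10), Acta2 (5.08 ± 0.098), Omd (4.11 ± 0.09) and Cp (4.01 ± 0.12) were higher with trametinib and Pmaip1 (-5.09 ± 0.095), Areg (-4.89 ± 0.10), Egr1 (-4.49 ± 0.099), Atg9b (-4.18 ± 0.081) and Slc4a11 (-4.10 ± 0.10) lower. All 23 cholesterol synthesis genes measured were higher (23 adjusted over the list alone, camera adjusted p = 1.67e-13, adjusted p = 0.0703 with an estimated correlation). Of 28 p53 targets, 25 were lower and 1 higher (1 up and 25 down adjusted over the list alone, camera adjusted p = 3.37e-10, adjusted p = 0.0703 with an estimated correlation).

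At 24 h the combination departed from the sum of its parts in 3997 genes, 2040 above it and 1957 below, 821 of them under the Bonferroni rule. Areg stood at 96.2 TPM in untreated cells, 108 TPM with chemotherapy, 2.68 TPM with trametinib and 21.8 TPM with the combination, an excess of 2.47 ± 0.15. Ptgs2 (2.25 ± 0.16), Atf3 (2.09 ± 0.13), the quinone reductase gene Nqo1 (2.10 ± 0.095) and Ugt1a6a (2.09 ± 0.18) also lay above the sum. Txnip, at 24.7, 621, 281 and 884 TPM in the same order, lay below it (-2.94 ± 0.19), as did Calb1 (-5.34 ± 0.98), Pih1d1 (-2.47 ± 0.69), Phkg1 (-2.31 ± 0.43) and Ccne2 (-2.12 ± 0.16). Chemokines lay above the sum in 5 and below it in 1 of 12 cases (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.384 with an estimated correlation). Ccl7 exceeded the sum by 1.79 ± 0.19, Ccl2 by 1.38 ± 0.17 and Cxcl2 by 1.02 ± 0.11. Cxcl2 was low in most libraries (mean 0.258 TPM over the 24), and the chemokine list includes Cxcl10. That list call ended with a pseudocount of 0.1, with the filter at 5 TPM and after rescaling (adjusted p = 0.179, 0.26 and 0.0602), and without trametinib replicate 3 (adjusted p = 0.0559). The mean excess of the list was 0.491 in the main fit and 0.539, 0.486 and 0.477 with the pseudocount, the filter and rescaling. Mitotic genes lay above in 27 and below in 2 of 34 cases (29 up and 2 down adjusted over the list alone, camera adjusted p = 5.51e-13, adjusted p = 0.221 with an estimated correlation). ATF4 targets lay above in 17 and below in 1 of 33 cases (18 up and 1 down adjusted over the list alone, camera adjusted p = 3.12e-07, adjusted p = 0.221 with an estimated correlation). Cholesterol synthesis genes lay below in 18 of 23 cases (20 adjusted over the list alone, camera adjusted p = 6.77e-14, adjusted p = 0.0706 with an estimated correlation). Interferon-stimulated genes lay below in 10 of 30 cases (1 up and 13 down adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.384 with an estimated correlation), with Samd9l at -1.26 ± 0.13. Their list call ended with the filter at 5 TPM (adjusted p = 0.169).

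Effects at the later time were tested against those at the earlier one. Each effect is relative to untreated cells of its time, which also changed between the times. The chemotherapy effect was higher at 24 h for Cd80 (2.47 ± 0.12), Ccne2 (2.36 ± 0.16), Pmaip1 (2.07 ± 0.14) and Cxcl10 (1.20 ± 0.16, adjusted p = 9.27e-06). In all 5668 genes differed (3566 higher at 24 h, 2102 lower, 1409 with the Bonferroni rule). Of these 62.9% were higher, or 49.3% after rescaling.
The trametinib effect was higher for Acta2 (2.43 ± 0.14) and for 19 of 23 cholesterol synthesis genes (19 adjusted over the list alone, camera adjusted p = 4.71e-17, adjusted p = 0.0318 with an estimated correlation). It was lower for Ccl7 (-2.66 ± 0.19), Ccl2 (-1.98 ± 0.17) and Cdkn1a (-1.54 ± 0.17), with 4810 genes in all that differed (2006 higher, 2804 lower, 1157 with the Bonferroni rule). The higher share was 41.7%, or 48.7% after rescaling. The difference for Cxcl10 was 0.14 ± 0.16 (adjusted p = 0.561).
For the combination 6249 genes differed (3186 higher, 3063 lower, 1868 with the Bonferroni rule), among them Thbs1 (2.13 ± 0.15), Tnfaip3 (1.97 ± 0.10), Cxcl2 (1.20 ± 0.11), Asns (-1.71 ± 0.075) and Cxcl10 (2.77 ± 0.16, adjusted p = 3.38e-10). The higher share was 51%, or 49.6% after rescaling. Cxcl2 was low in most libraries (mean 0.258 TPM over the 24). Calls against separate controls at each time overlapped: 893 genes were higher with chemotherapy at both times where 496.9 are expected of independent lists, 2673 with trametinib (1462 expected) and 3060 with the combination (1920.6 expected). Genes lower at both times numbered 839 (411 expected), 1608 (625 expected) and 1333 (593 expected).

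Untreated cells also changed between 6 h and 24 h. S phase genes were lower at 24 h in 29 of 32 cases (30 adjusted over the list alone, camera adjusted p = 6.96e-10, adjusted p = 0.213 with an estimated correlation), with Cdc6 at -1.42 ± 0.078. Ribosome biogenesis genes were lower in 26 of 27 cases (27 adjusted over the list alone, camera adjusted p = 3.89e-12, adjusted p = 0.213 with an estimated correlation), with Nop2 at -1.36 ± 0.072. Heat shock genes were lower in 10 of 13 cases (11 adjusted over the list alone, camera adjusted p = 4.51e-05, adjusted p = 0.213 with an estimated correlation). Folate and nucleotide synthesis genes were lower in 25 and higher in 3 of 32 cases (3 up and 25 down adjusted over the list alone, camera adjusted p = 3.41e-05, adjusted p = 0.236 with an estimated correlation). Tyms changed by -1.25 ± 0.072. Chemokines were higher in 8 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.0156, adjusted p = 0.236 with an estimated correlation). Ccl2 (1.29 ± 0.12) was among them. Trp53inp1 (2.20 ± 0.11), Ddit3 (2.11 ± 0.068), the heavy chain gene H2-K1 (1.19 ± 0.11) and the autophagy receptor gene Sqstm1 (0.95 ± 0.051) were higher as well. Cxcl10 was higher by 0.28 ± 0.12 (adjusted p = 0.0454), a call that ended with the Bonferroni rule, without a filter, and in turn without 5 of the 6 libraries (0.25 to 0.29), 6 h replicate 3 being the exception (0.32). The test called 7649 genes, 3696 higher at 24 h and 3953 lower, and 3202 under the Bonferroni rule. The higher share of 48.3% became 55.4% after rescaling, so here too the direction with more genes depended on the scaling.

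**Figure D2:**
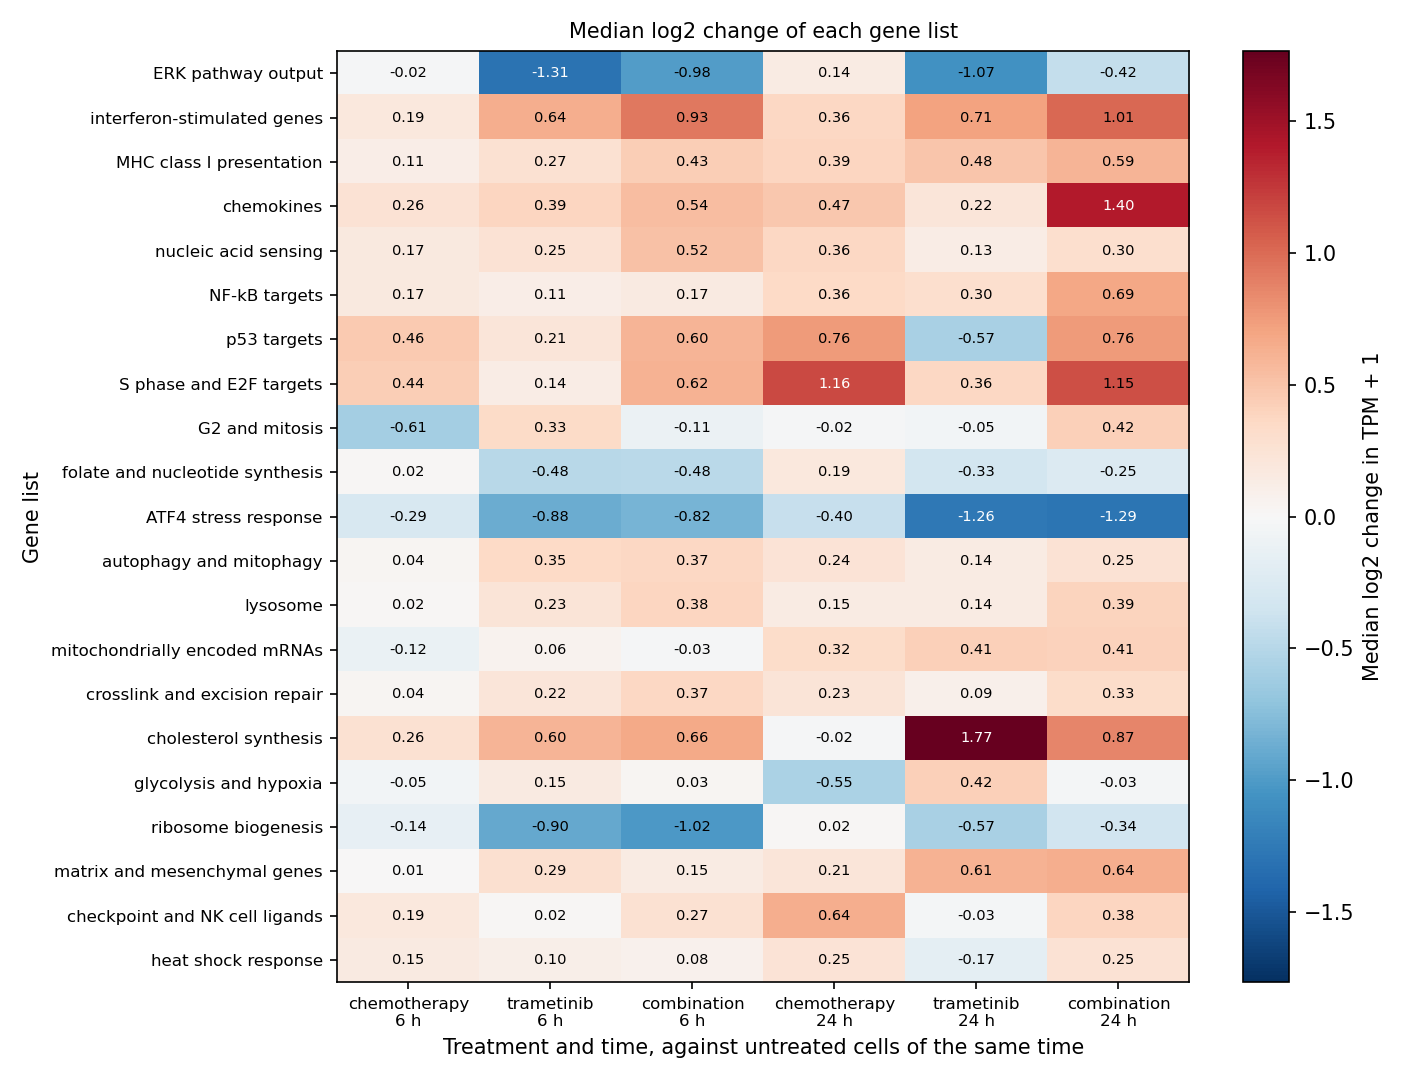
Median log2 change in TPM + 1 over the measured members of each of the 21 gene lists, for the 3 treatments against untreated cells at 6 h and 24 h, as a colour scale with the value printed in each cell. Cholesterol synthesis genes reach a median of 1.77 with trametinib at 24 h.

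Markers of other cell types were mostly near 0 TPM in these cultures. Of 12 macrophage markers 2 reached a mean of 1 TPM over the 24 libraries, Cd14 (15.2 TPM) and Lyz2 (1.09 TPM). The T or NK cell (7), B cell (4), lung epithelium (6) and red cell (4) lists had no member at that level, with Cd3d (0.765 TPM) and Hba-a1 (0.724 TPM) the highest. Pecam1 (4.25 TPM) was the only 1 of 6 endothelial markers to reach it. Fibroblast markers reached it in 4 of 5 cases, from Col1a1 (1.74 TPM) to Col3a1 (478 TPM).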

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

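For Cxcl10, the tests of macrophage RNA and of library scaling were chosen after the result was seen, and the other tests before.

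At 24 h Cxcl10 in the combination exceeded the sum of the separate effects by 1.47 ± 0.16 on the log2 scale. RNA from macrophages would bring the abundant transcripts of those cells, yet 8 macrophage markers had a median of 0 TPM in the combination libraries, with Fcer1g highest at 0.596 TPM. Of the 12 macrophage markers read as levels, these 8 leave out the only ones that reached a mean of 1 TPM. Those were Cd14, at 14.9 ± 1.63 TPM in the combination and 12.4 ± 1.15 TPM in untreated cells, and Lyz2, at 3.57 ± 0.351 and 0.39 ± 0.056 TPM. Low levels of the 8 markers could be foreseen in cultures of a cell line, so the marker test adds little. After rescaling the excess was 1.45, and with any 1 of the 12 libraries of that time left out it was at least 1.37. Both outcomes could be foreseen. The scaling factors at 24 h lay between 0.934 and 1.04, and every combination library lay above all others of that time. These values argue against library scaling or a single library as the whole cause, but add little to the levels themselves. Joint exposure to the drugs, which the design names, may underlie the excess, and this hypothesis was not tested by other means.

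The 1150 of 11496 protein-coding genes with the longest genomic span covered at least 112903 bases. After 24 h of chemotherapy their median change was -0.19, against 0.10 for the others. The gap was -0.29 (95% resampling interval -0.33 to -0.26), with 557 of the long genes lower and 189 higher. Here and below genes were resampled and the libraries kept fixed, so these intervals do not measure the spread between libraries. Mature transcript length is argued against, since the gap among genes of similar mature length was -0.31 (-0.34 to -0.27), and low expression of long genes by a gap of -0.25 (-0.31 to -0.20) among genes with a mean of at least 20 TPM. The test set for exposure to chemotherapy was the gap when it was added to trametinib. At 24 h that gap was -0.087 (-0.109 to -0.061), short of the -0.2 set in advance as evidence for exposure. The gap lay above -0.1, which had been set in advance as evidence against exposure, although its interval spans -0.1. This test cannot tell what gave the gap without trametinib, since the effect of chemotherapy may differ beside trametinib. At 6 h the gaps were -0.32 (-0.342 to -0.302) for chemotherapy and -0.225 (-0.237 to -0.21) for chemotherapy added to trametinib. The latter was past the -0.2 that had been set for 24 h.

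Rps12, a ribosomal protein gene, stood at 0.008 ± 0.013 TPM in the combination libraries at 24 h and 425 ± 375 TPM in untreated ones. Reads assigned to near-identical copies may account for this: with Rps12-ps3, Rps12l1 and Rps12-ps9, which share 90.4%, 73.9% and 63.7% of its 31-base words, the sums were 1464 ± 212 and 1387 ± 277 TPM, a ratio of 1.06. The sum was less stable in the other groups at 24 h, with 907 ± 835 TPM for chemotherapy and 895 ± 409 TPM for trametinib. The ratio is therefore limited evidence. A single library is argued against, since 3 of 3 combination libraries lay below every untreated library of that time. Low values also occurred in untreated replicate 2 at 24 h (4.2 TPM), chemotherapy replicate 2 at 24 h (listed at 0), trametinib replicate 3 at 24 h (0.155 TPM) and combination replicate 3 at 6 h (12.3 TPM). A fall of Rps12 mRNA itself stays open.

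Effects that differed between 6 h and 24 h in limma's test of the difference numbered 5668 genes for chemotherapy, 4810 for trametinib and 6249 for the combination. With chemotherapy the effect at 24 h minus that at 6 h was 1.20 for Cxcl10, 2.07 for Pmaip1, 1.85 for Cdc6, 1.32 for Mdm2, 1.30 for Btg2, 0.76 for Tyms and 0.54 for Irf1. With trametinib it was 2.43 for Acta2, 2.37 for Cbr2, 1.60 for Tgfbi, 0.56 for Cxcl5, -0.69 for Asns, -1.10 for Cth, -1.32 for Mmp3 and -2.22 for Areg. With the combination it was 2.77 for Cxcl10, 2.09 for Anxa8, 1.46 for Tgfbi, 0.86 for Lgals9, 0.66 for Cryab, 0.15 for B2m, -0.55 for Cdkn1a and -0.62 for Trib3. Each effect is relative to untreated cells of its time, so a change of the untreated cells enters the difference. For S phase genes the mean difference was 0.856 with chemotherapy and 0.623 with the combination. Untreated cells alone gave a mean of -0.634 for this list at 24 h against 6 h. Cdc6 and Tyms were also lower in untreated cells at 24 h than at 6 h. Only lists given above for a treatment against untreated cells at both times were looked at here, so others may differ too. Of these, the lists whose difference passed camera with chemotherapy were S phase (adjusted p = 6.65e-13), cholesterol synthesis (0.0138) and p53 targets (0.0457). With the correlation estimated none of them passed (0.180, 0.573 and 0.627). The call of p53 targets also ended with a pseudocount of 0.1 (adjusted p = 0.0877), the filter at 5 TPM (0.0946) and the replicate term (0.0599), and without any of 5 libraries in turn (0.0547 to 0.0742). With trametinib they were cholesterol synthesis (4.71e-17), ribosome biogenesis (2.08e-06), ATF4 targets (0.000901) and interferon-stimulated genes (0.0257), of which only cholesterol synthesis passed with the correlation estimated (0.0318, the others 0.377). The interferon call also ended with a pseudocount of 0.1 (0.114) and the filter at 5 TPM (0.535). With the combination they were mitotic genes (6.31e-10), S phase (1.39e-09), ATF4 targets (0.00468), ERK output (0.00468) and chemokines (0.0141), and with the correlation estimated none passed (0.332, 0.332, 0.449, 0.709 and 0.396). The chemokine call also ended with a pseudocount of 0.1 (0.136) and the filter at 5 TPM (0.827).

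Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, in the 13 comparisons of 2 groups. In each, the real split alone (1 of 10) gave a count as large. All other splits mix libraries of both groups, which widens the spread within groups, so their low counts give no rate of false calls. The real counts for chemotherapy, trametinib and the combination against untreated cells were 3116, 6892 and 7347 at 6 h and 7447, 7383 and 7972 at 24 h. For the combination against chemotherapy and against trametinib, and trametinib against chemotherapy, they were 7046, 2373 and 7114 at 6 h and 6731, 6208 and 8382 at 24 h, and for untreated cells over time 7649. The highest count of another split was 1, or 0 in limma's test for trametinib and the combination against untreated cells at 6 h, the combination against chemotherapy at 6 h, trametinib against chemotherapy at 24 h and untreated cells over time, with at most 1284, 939, 2430, 1445 and 782 genes at an unadjusted p under 0.05.

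For contrasts of 4 groups, 100 regroupings within each time were drawn. The 12 genes beyond the sum at 6 h were matched or passed by 14 of 100 splits, with a highest other of 5162, and a count that far above the real one points to the structure of the samples, whose treatments the regroupings mix. At 24 h 3 of 100 splits reached 3997 (highest other 5866). The time differences were reached by 2 splits for chemotherapy (5668, highest other 6825), 4 for trametinib (4810, highest other 5348) and 2 for the combination (6249, highest other 8511). Because the regroupings mix libraries with real treatment effects, and some called more genes than the real grouping, they are no reference without change, and whether chance can be excluded stays open for these 5 counts.

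Transcripts left out of the gene values also carried signal, since of 1017 tested 74 were higher and 135 lower with chemotherapy, 73 and 60 with trametinib and 97 and 81 with the combination at 24 h than in untreated cells. At 6 h limma called 52 higher and 21 lower with trametinib, 82 and 19 with the combination, and 0 with chemotherapy against untreated cells or in the combination against trametinib (80 and 111 of 1017 at an unadjusted p under 0.05).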

How the results depend on the processing

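The alternatives and their thresholds were chosen before the data were examined. With a pseudocount of 0.1, no filter, a filter at a mean of 5 TPM, rescaled TPM, 1 fit per time point, the replicate term or 1 prior variance, the 18 counts of called genes stayed within 1.5 times the values given, except that of genes beyond the sum at 6 h. With 1 fit per time point only the 14 counts within a time could be had. The 6 counts of calls shared by 6 h and 24 h stayed within 1.5 times under these settings and with each library left out. Of 321 named changes other than Cxcl10, 318 kept their direction and call under each setting that gave a value, the exceptions being Cryab, Ddit3 and Vldlr beyond the sum at 6 h, which kept their direction. Most of these genes were named because they were called with large changes or small p, so this outcome could largely be foreseen. The Bonferroni rule and the minimum change were not applied to them. Of 109 list results given, 103 were called by camera, and 24 of these held with the correlation estimated while 79 did not. With fry, which does not compare a list with other genes, 3 further list results passed, and no list reversed under these settings. TPM carries no depth, so the counting error of low genes is not known.

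For genes beyond the sum at 6 h (12), the count was 7 with a pseudocount of 0.1, 0 with 1 limma fit per time point (1183 genes at an unadjusted p under 0.05), 4 with the Bonferroni rule, 1 with a log2 change of at least 1, and 3 to 41 with 1 library left out. Adding a block for the replicate number gave 4 in place of 12 and moved no other count beyond 1.5 times. Pairing of the libraries by number was not shown, though 3 libraries per group cannot exclude it. Of 36 pairs with the same number, 10 had deviations that correlated above 0.1 (range -0.358 to 0.335). Among the 24 libraries, 9 were closest to a library of their own number. Apart from fewer degrees of freedom within 1 time point, the cause was not tested.

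The Bonferroni rule and the minimum change lower counts by construction. The Bonferroni rule gave 566, 2696 and 3297 genes for chemotherapy, trametinib and the combination against untreated cells at 6 h, and 3057, 3122 and 3783 at 24 h. It gave 2711 and 2526 for the combination against chemotherapy at 6 h and 24 h, 435 and 2004 against trametinib, 2868 and 4247 for trametinib against chemotherapy, 821 beyond the sum at 24 h, 1409, 1157 and 1868 for the time differences of the 3 treatments and 3202 for untreated cells. With a log2 change of at least 1 the counts in the same order were 47, 619, 895, 788, 916 and 1200 against untreated cells, 562, 627, 42, 387, 647 and 1443 between treatments, 297 beyond the sum, 577, 482 and 848 for the time differences and 655 for untreated cells.

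Cxcl10 kept its direction in the 18 comparisons wherever it was called. With a pseudocount of 0.1 it also passed for chemotherapy against untreated cells (0.79) and the combination against trametinib (0.90) at 6 h, since less is added to low values. The combination against untreated cells at 6 h (0.33) did not pass the Bonferroni rule and ranged from 0.27 to 0.41 with a library left out, the call ending without untreated replicate 1 or 2 or combination replicate 3. Untreated cells at 24 h against 6 h (0.28) did not pass the Bonferroni rule or without a filter, and ranged from 0.25 to 0.32, the call ending without each library but 6 h replicate 3. The filter at a mean of 5 TPM removed Cxcl10 and gave no value for it. With a library left out, the 6 h values that were not called ranged from 0.12 to 0.31 for chemotherapy, -0.007 to 0.12 for trametinib, 0.019 to 0.21 for the combination against chemotherapy, 0.22 to 0.36 against trametinib, -0.26 to -0.068 for trametinib against chemotherapy and -0.033 to 0.16 beyond the sum. The trametinib effect over time ranged from 0.071 to 0.19. None of these passed. For these small changes the cause was not tested.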

Other observations

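Trametinib at 24 h also raised genes of glycolysis and the hypoxia response in 17 of 23 cases and lowered 3 (18 up and 3 down adjusted over the list alone, camera adjusted p = 0.00751, adjusted p = 0.471 with an estimated correlation), with Adm, which encodes adrenomedullin, at 1.62 ± 0.095 and the lactate dehydrogenase gene Ldha at 0.67 ± 0.05. Bnip3, a mitophagy receptor gene, rose by 1.51 ± 0.12 and the cathepsin gene Ctsl fell (-1.37 ± 0.058). With chemotherapy at 24 h, 20 of 23 genes of the glycolysis list had fallen (camera adjusted p = 0.21 with an estimated correlation).
Between trametinib and chemotherapy at 24 h that list was higher with trametinib in 19 and lower in 1 of 23 cases (19 up and 1 down adjusted over the list alone, camera adjusted p = 5.13e-07, adjusted p = 0.183 with an estimated correlation).

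Mitochondrially encoded mRNAs made up 9.70 ± 0.376% of TPM in untreated libraries at 24 h, 11.5 ± 0.771% with chemotherapy, 11.4 ± 0.119% with trametinib and 11.6 ± 0.494% with the combination (mean ± SD, n = 3). Ribosomal protein mRNAs made up 16.0 ± 0.51% and, in the same order, 14.0 ± 0.931%, 13.6 ± 0.828% and 12.5 ± 0.285%. The span gap between long genes and the others was 0.20 in untreated cells at 24 h against 6 h (95% resampling interval 0.177 to 0.235) and 0.23 in the contrast of the combination with the sum of its parts at 24 h (0.198 to 0.262).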
